A study of Arabidopsis thaliana with 2 samples.

How the data were processed

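Messenger RNA abundance was measured in developing Arabidopsis thaliana seeds by sequencing 2 libraries. One library came from plants carrying the soybean gene GmPSKγ1, which encodes a precursor of the peptide hormone phytosulfokine, under a promoter labelled OLEOp. The other came from plants carrying the construct labelled GmPSKγ1tc, which the submitters name as the control and label with the same promoter. Both samples were taken at 10 DAP (the age as labelled). Per the labels' design text, RNA of 3 individual lines per genotype was pooled before sequencing, so each genotype is represented by 1 library and the spread between lines cannot be recovered.

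The deposited values are FPKM, computed by the authors: reads or fragments per kilobase of gene model, scaled to the size of the library. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build TAIR10 were used. The program that computed FPKM, its version, the annotation release and the handling of reads that map to several places are not given in the sources used here. The libraries were made from total RNA after DNase treatment, per the labels' protocols; whether they keep the strand is not stated, so a gene and an antisense partner cannot be told apart. Both tables list the same 33602 gene models with their positions. Of these, 32835 matched a locus tag of the reference annotation (assembly TAIR10.1), which was used for gene names, gene types and exon lengths; coordinates below are those of the deposited tables (TAIR10). The start and end agreed between the tables and the reference for 10599 models.

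Read depth was estimated from the FPKM values themselves. In genes with a single exon and no overlapping neighbour, low values fell on steps of 0.0610 FPKM × kilobase in the GmPSKγ1 library and 0.0653 in the control. If a step is 1 read or fragment, the libraries were scaled to 16.4 M and 15.3 M reads (M, 10 to the power of 6). Below 200 reads, 97.5% of the values of such genes in GmPSKγ1 and 99.5% in the control came out whole within 0.05, where chance gives 10%. For other gene models with 1 transcript and unchanged ends the shares were 92.1% and 99.6%. Reads per gene were estimated from these steps and the exon length of the reference. They are exact only where model ends match, and approximate elsewhere. An exact (Clopper-Pearson) 95% interval of the ratio between the libraries was computed from them for gene models that overlap no other. The use of approximate counts was decided after the data were seen, because few of the genes past the threshold had exact ones. These intervals cover counting error only, not the spread between plants, lines or library preparations. Reads without molecular identifiers are not independent molecules.

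Each gene was compared as the log2 ratio of GmPSKγ1 over GmPSKγ1tc after adding a pseudocount of 1 to FPKM, which understates the difference of genes near or below 1 FPKM. Genes with a mean FPKM of at least 1 over the 2 libraries were counted (17816), and a size of 2-fold on this scale was the threshold. No significance test between genotypes can be made with 1 library each, and no p-value is given. Of the 33602 models, 4329 overlap another listed model and 89 share its exact coordinates; ratios of such models are uncertain, since the division of reads between them is not known.

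Before the data were examined, 25 gene lists with 406 entries were fixed; none was left out for a missing identifier or a conflicting name. Members were chosen from general knowledge, and agreement of identifiers and names does not show that each belongs to its list. A list was described by the median log2 ratio of its members with a mean FPKM of at least 1, with a 95% order-statistic interval where at least 6 were measured. Its percentile was taken among 10000 random lists of the same size, drawn with replacement from the same 20 bins of mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile. By chance 1.25 of 25 lists would do so if genes were independent, which co-regulated genes are not. The percentile describes these 2 libraries and does not test the genotypes.

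The rule for naming genes was also fixed beforehand. It takes the 15 largest and 15 smallest log2 ratios among genes with an FPKM of at least 5 in 1 library or both, leaving out structural RNAs, transposons and organelle genes. It adds every gene of the phytosulfokine list and, from each other list, the 3 members with the largest absolute ratio and the most abundant one. Not every gene it selects is named. Any other gene named, such as CRA1, HSFA2 and the suberin genes, was chosen after its values were seen. Alternatives were pseudocounts of 0.1 and 5, no minimum or a minimum mean FPKM of 5, and thresholds of 1.5-fold and 4-fold. The 3 rescalings were by the median ratio, without the 50 most abundant genes, and to a sum of 1000000 in each library, which multiplies the deposited values by 1.45 in both. A further one, to the mean of the 2 deposited sums, was added after the data were seen. List means and unmatched random lists were further alternatives.

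On simulated data with Poisson counts at these depths for the comparison of GmPSKγ1 with GmPSKγ1tc, over the 17816 genes, 100 of 100 genes changed 3-fold and 100 of 100 changed 4-fold were recovered past the threshold. With a pseudocount of 1, a 3-fold change can pass it only where the lower library has at least 1 FPKM. This recovery therefore does not extend to more weakly expressed genes. The counting interval held a ratio of 1 for 96.4% of 2000 unchanged genes. Of 200 unchanged lists of 20 genes, 6% lay outside the central 95% of random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Expression of the soybean transgene was not analysed here.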

Results

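Transcript abundance was compared between 2 pooled seed libraries at 10 DAP, 1 from plants carrying a construct of the soybean phytosulfokine precursor gene GmPSKγ1 and 1 from GmPSKγ1tc control plants. Phytosulfokine is a small sulfated peptide known to promote cell growth. The libraries were scaled to about 16.4 M reads for GmPSKγ1 and 15.3 M reads for the control. FPKM of at least 1 was listed for 17841 and 17727 gene models, and 10506 of 33602 models were listed at 0 in both. Each value is from a single library, so the differences below have no replicate check.

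The most abundant transcript in both libraries was SESA3, which encodes a seed storage albumin, at 27054 FPKM in GmPSKγ1 and 34812 FPKM in the control. The 10 most abundant genes took 16.7% of all FPKM in GmPSKγ1 and 20.9% in the control. Across the 17816 genes with a mean of at least 1 FPKM, log2(FPKM + 1) of the libraries correlated with a Pearson r of 0.98 and a Spearman rho of 0.98; this is across genes, which are not independent replicates. The median log2 ratio was 0.05, with quartiles of -0.11 and 0.21, and 94.2% of genes differed by less than 1.5-fold.

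To find genes that differed between the libraries, genes were ranked by their ratio. At least 2-fold higher FPKM in GmPSKγ1 was seen for 73 genes and at least 2-fold lower FPKM for 146, together 1.23% of those measured. These counts depend on how low values are treated: they were 179 and 231 with a pseudocount of 0.1, 14 and 54 with a pseudocount of 5, and 30 and 85 with a minimum mean FPKM of 5. The lowest values included genes annotated as extensin family, hydroxyproline-rich, cupin and small heat shock proteins. With a threshold of 1.5-fold the balance turned, with 557 genes higher and 478 lower. Poisson sampling at these depths alone gave a median of 8 genes in each direction over 100 draws, and at most 25 in total. Of the higher genes, 27 were models that overlap another, as were 25 of the lower ones. Counting intervals excluded a ratio of 1 for 42 of the 46 higher genes that overlap no other model, and for 118 of the 121 lower ones. These genes were picked for their ratio in the same values, so this is not independent evidence. Exact counts were available for 2 of the higher and 14 of the lower genes, and the other intervals rest on approximate counts.

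Neighbouring pairs of related genes led the lower group. AT2G41390 (chromosome 2, 17257380 to 17258196) and AT2G41400 (chromosome 2, 17259457 to 17260120), which encode proteins of the pollen Ole e 1 allergen and extensin family, had 0.448 and 0.643 FPKM in GmPSKγ1 against 30.7 and 23.0 FPKM in the control. The respective read counts were 6 against 384 and 7 against 234, and the control was 68.5-fold higher for AT2G41390 (95% counting interval 31.2 to 188). The cupin genes AT3G04190 (chromosome 3, 1101878 to 1102763) and AT3G04170 (chromosome 3, 1094621 to 1095665) had 0.398 and 0.139 FPKM in GmPSKγ1 against 21.4 and 15.2 FPKM in the control, on 5 and 2 reads against 251 and 204. The ratio of control to GmPSKγ1 for AT3G04170 was 109, with a counting interval of 29.8 to 907.

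Genes annotated as hydroxyproline-rich glycoproteins were among the 15 lowest. PELPK1 (AT5G09530; chromosome 5, 2959734 to 2961271) had 13.9 FPKM in GmPSKγ1 and 129 FPKM in the control, 9.23-fold higher in the control (counting interval 8.30 to 10.3). AT4G38080, of the same annotated family, had 12.9 against 96.3 FPKM, and AT2G22510 had 2.16 against 31.4 FPKM. AT5G44550 and AT3G06390, from a family of uncharacterized membrane proteins (UPF0497), had 0.569 and 0.858 FPKM in GmPSKγ1 against 13.4 and 11.6 FPKM. AT1G19900, a glyoxal oxidase-related gene, had 12.0 against 87.3 FPKM. AT5G37690, an SGNH hydrolase-type esterase gene, had 0.0883 against 6.10 FPKM, the former on 2 reads, and the control was 69.1-fold higher (counting interval 19.6 to 603). The small heat shock protein gene AT1G07400 (chromosome 1, 2274943 to 2275758) had 18.1 against 122 FPKM, 6.73-fold higher in the control (counting interval 5.90 to 7.73). AT1G47395, which encodes an uncharacterized protein, had 0.651 against 9.58 FPKM. AT3G60730, a pectin methylesterase inhibitor family gene whose model overlaps another, had 0.182 against 9.41 FPKM.

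Among the genes higher in GmPSKγ1, the leading values stood at gene models that share their position with another. GBF6 (AT4G34590; chromosome 4, 16521861 to 16523230), a bZIP transcription factor gene, was listed at 143 FPKM in GmPSKγ1 and 0.381 FPKM in the control. bZIP2 (AT2G18160; chromosome 2, 7898012 to 7899242) was listed at 51.3 FPKM in GmPSKγ1 and at 0 in the control, while AT2G18162, listed with the same coordinates, had 55.1 and 113 FPKM. Summed over both models, that locus had 106 and 113 FPKM. The GBF6 locus, summed in the same way, had 143 and 0.763 FPKM. AT1G64142, AT5G64552, AT3G45242, AT1G23149 and AT5G64550 among the 15 highest also share their coordinates with another model, and SUVH6 (6.03 against 0.749 FPKM) and AT5G05965 (11.3 against 2.84 FPKM) overlap one. AT5G53588, among the 15 lowest, shares its coordinates with another model too and was listed at 0 in GmPSKγ1 and 5.91 FPKM in the control.

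The other genes among the 15 highest had models that overlap no other. GT72B1 (AT4G01070; chromosome 4, 461592 to 463556), a UDP-glycosyltransferase gene, had 9.61 FPKM in GmPSKγ1 and 0.687 FPKM in the control, 14.0-fold higher (counting interval 8.88 to 22.1). AT4G20980, which encodes a subunit of translation initiation factor eIF-3, had 9.51 against 0.902 FPKM. The HSP70 family gene AT3G09440 had 35.0 against 8.81 FPKM, opposite in direction to most genes of the heat shock list. It has paralogs of similar sequence, so its value is uncertain where the authors' counting divided reads between them. The dormancy/auxin associated gene AT2G33830 had 30.1 against 9.22 FPKM, 3.26-fold higher (counting interval 2.73 to 3.91). AT2G27385, a pollen Ole e 1 allergen and extensin family gene, had 23.3 against 7.10 FPKM. AT4G05070, a wound-responsive family gene, was listed at 15.5 FPKM in GmPSKγ1 and at 0 in the control, on about 134 reads against 0. A missed estimate in the control cannot be told from a true difference for this gene.

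The 25 gene lists were then compared. Of these, 8 had medians outside the central 95% of matched random lists, 1 above and 7 below.

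**Figure D1:**
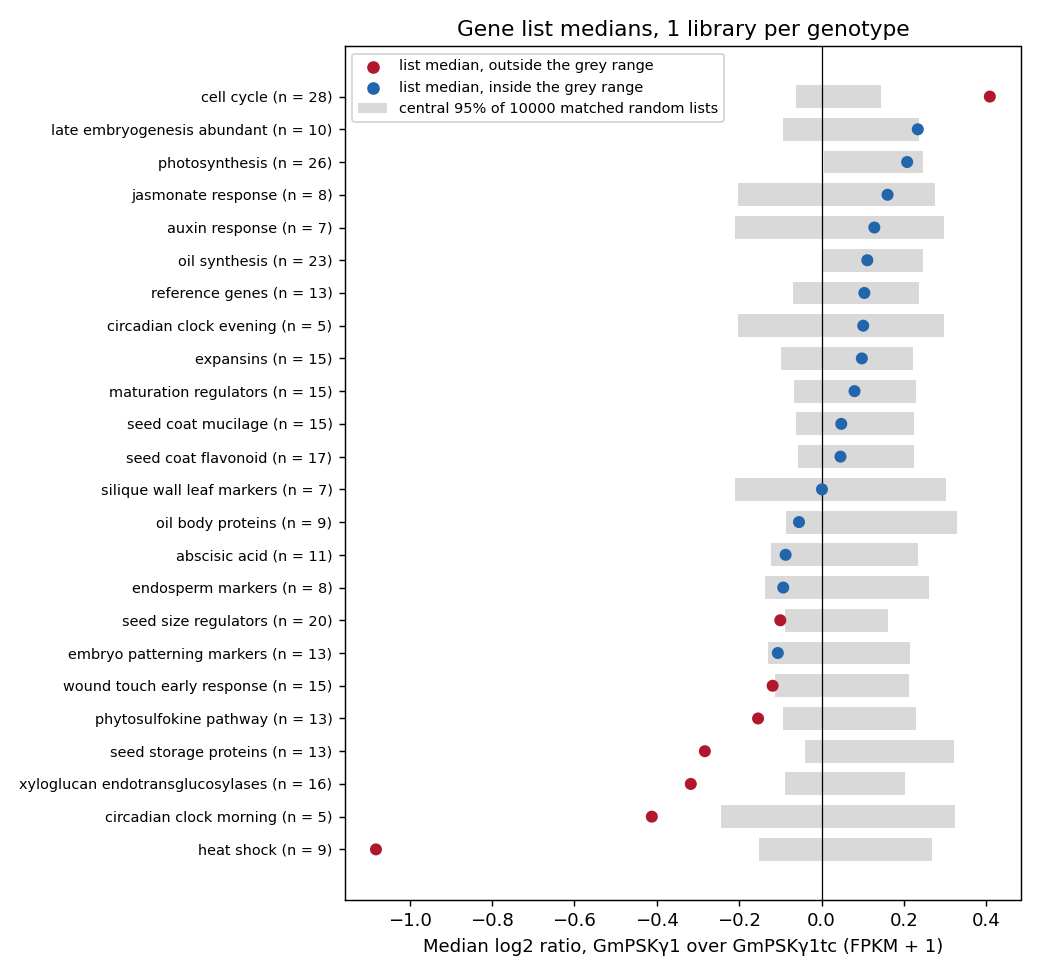
Median log2 ratio of GmPSKγ1 over GmPSKγ1tc (x axis, FPKM + 1) for each gene list with at least 5 measured members (y axis, n = members measured); grey bars span the central 95% of 10000 random lists matched on mean expression. The cell cycle list (0.41) lies above its bar, and heat shock (-1.08), morning clock (-0.41), xyloglucan endotransglucosylase (-0.32), storage protein (-0.28), phytosulfokine (-0.15), wound and touch (-0.12) and seed size (-0.10) lists lie below theirs, the last 2 narrowly.

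Cell cycle genes were higher in GmPSKγ1 in 28 of 28 cases, and in 26 of 28 when the libraries were rescaled by the median ratio or without the 50 most abundant genes. Their median log2 ratio was 0.41 (95% interval 0.31 to 0.49 over members), or 1.33-fold, above all 10000 random lists (percentile 100). No member reached 2-fold on the log2(FPKM + 1) scale. The mitotic cyclin gene CYCB1;3 had 7.94 FPKM in GmPSKγ1 and 3.88 FPKM in the control, 2.04-fold without the pseudocount (counting interval 1.59 to 2.60). PCNA1, which encodes the sliding clamp of DNA replication, had 18.7 against 10.3 FPKM, and the mitotic kinase gene CDKB1;1 had 11.4 against 6.67 FPKM. KN, which encodes the cytokinesis syntaxin KNOLLE, was the most abundant member at 121 against 96.0 FPKM.

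Genes of the heat shock list were lower in GmPSKγ1 for 8 of 9 measured members, 5 of them at least 2-fold. The median was -1.08 (interval -1.47 to -0.01), below all random lists (percentile 0). Over all 84 measured genes with heat shock in their annotated product, screened after the fact, the median was -0.10 (interval -0.18 to -0.04, percentile 0). Of these, 57 were lower, 7 of them at least 2-fold, and 27 higher, 1 of them at least 2-fold. The keyword takes in 22 genes annotated as DnaJ heat shock N-terminal domain-containing and 9 of the DnaJ heat shock family. It leaves out genes annotated as HSP20-like chaperones, such as HSP17.6C and AT1G07400. For the 21 measured genes annotated as HSP20-like chaperones, the median was -0.10 (interval -0.59 to 0.07, percentile 0.77). Of these, 13 were lower, 5 of them at least 2-fold, and 8 were higher. HSP17.4 and HSP17.6A carry other product names and are not in this set. HSP17.4, a cytosolic small heat shock protein gene, had 7.58 FPKM in GmPSKγ1 and 38.0 FPKM in the control; its model overlaps another. The most abundant member, the HSP70 gene AT3G12580, had 126 against 283 FPKM, with the control 2.25-fold higher (counting interval 2.17 to 2.32). HSP17.6A had 2.71 against 7.97 FPKM and HSP17.6C had 0.377 against 2.82 FPKM. HSFA2, the gene of a heat stress transcription factor, had 8.02 against 18.1 FPKM. Genes of the early response to wounding and touch, a marker of handling, were also lower for 11 of 15 members, with a median of -0.12 (-0.20 after rescaling without the 50 most abundant genes) at percentile 2.14, which became 2.86 when random lists were also matched on gene length. CML38, a calmodulin-like gene, had 1.81 against 3.39 FPKM, WRKY40 had 0.868 against 1.59 FPKM, and RRTF1 had 5.73 against 7.97 FPKM. The models of WRKY40 and RRTF1 each overlap another.

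Seed storage protein genes were lower in GmPSKγ1 for 11 of 13 members. The median log2 ratio was -0.28 (interval -0.67 to -0.19), below all random lists, and the list took 13.3% of all FPKM in GmPSKγ1 against 16.9% in the control. CRU4 (AT1G03890), a cruciferin-type globulin gene, had 369 against 731 FPKM, with the control 1.98-fold higher (counting interval 1.93 to 2.03). SESA4 had 11073 against 19092 FPKM, and CRB had 6116 against 9733 FPKM. CRA1, the other way round, had 8831 FPKM in GmPSKγ1 and 6493 FPKM in the control. Storage albumin genes are similar in sequence, so reads could be divided between them and the values of single genes are uncertain. However, SESA1, SESA2, SESA3, SESA4 and SESA5 were each lower in GmPSKγ1 (log2 ratios -0.19, -0.28, -0.36, -0.79 and -0.52). Division of reads among these genes alone would not lower each of them.

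Oil body protein genes did not stand apart. Their median was -0.05 (interval -0.16 to 0.06, percentile 4.36), with 4 of 9 members higher. OLEO1, the most abundant oleosin gene, had 9925 FPKM in GmPSKγ1 and 10689 FPKM in the control, and its model overlaps another. OLEO4 had 1379 against 1750 FPKM and OLEO5 had 3740 against 4182 FPKM. The oleosin gene AT2G25890, with the largest absolute log2 ratio of the list, had 42.7 against 30.9 FPKM (ratio interval 1.22 to 1.57). Genes of oil synthesis had a median of 0.11 (percentile 42.6). FAD3, the gene of the endoplasmic reticulum linoleate desaturase, had 281 against 440 FPKM, while KAS1, of plastid fatty acid synthesis, had 222 against 164 FPKM. Regulators of seed maturation had a median of 0.08 (percentile 48.7), with LEC2 at 4.68 against 3.37 FPKM, AGL15 at 161 against 128 FPKM and FUS3 at 249 against 235 FPKM. Late embryogenesis abundant genes, which protect seeds during drying, had a median of 0.23 (interval -0.21 to 0.64, percentile 97.2), with 7 of 10 members higher. The member AT3G17520 had 88.1 against 48.9 FPKM and RAB18 had 7.25 against 4.30 FPKM, while AT3G15670 had 11.9 against 17.7 FPKM. PER1, the most abundant member of the list, is annotated as a 1-cysteine peroxiredoxin gene and had 657 against 698 FPKM.

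Xyloglucan endotransglucosylase genes, whose products cut and rejoin cell wall xyloglucan, were lower in GmPSKγ1 for 13 of 16 members, with a median of -0.32 (interval -0.46 to -0.06, or -0.15 with a pseudocount of 5), below all random lists. XTH16 had 41.8 against 70.8 FPKM, XTH9 had 22.4 against 32.3 FPKM and XTH25 had 4.21 against 6.23 FPKM. The most abundant member, XTH22, had 131 against 136 FPKM, and its counting interval of 0.913 to 1.01 for the ratio of GmPSKγ1 to control included 1. Expansin genes had a median of 0.10 (percentile 66.3), with 9 of 15 higher. EXPB1 had 65.1 against 48.9 FPKM and EXLA1, whose model overlaps another, had 430 against 474 FPKM.

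Because the construct carries a phytosulfokine precursor gene, the endogenous pathway was examined. Its median was -0.15 (interval -0.33 to 0.14, percentile 0.47; -0.09 with no minimum FPKM), with 9 of 13 measured members lower and none past 2-fold. PSKR1, which encodes the main phytosulfokine receptor, had 4.67 FPKM in GmPSKγ1 and 6.54 FPKM in the control, a ratio of 0.715 (counting interval 0.609 to 0.838). The second receptor gene PSKR2 had 4.86 against 6.12 FPKM. CNGC17, a cation channel gene, had 7.20 against 9.76 FPKM. Among the precursor genes PSK4 was the most abundant, with 774 against 820 FPKM, followed by PSK1 with 74.6 against 64.4 FPKM and PSK3 with 38.6 against 43.1 FPKM (ratio interval 0.791 to 1.01). PSK2 had 1.23 against 1.80 FPKM and PSK5 had 1.03 against 0.735 FPKM, with counting intervals that included 1. PSK6 was listed at 0 in both libraries. TPST, the gene of the tyrosylprotein sulfotransferase that matures these peptides, had 8.83 against 7.90 FPKM, and the interval of its ratio (0.949 to 1.32) included 1. SBT1.1, a subtilase gene whose model overlaps another, had 69.0 against 79.2 FPKM. The co-receptor gene BAK1 had 11.0 against 12.3 FPKM (interval 0.787 to 1.01), and the proton pump genes AHA1 and AHA2 had 171 against 183 and 27.4 against 26.4 FPKM, the latter pair with an interval that included 1 (0.966 to 1.11). PSY1, of a related sulfated peptide, had 24.0 against 16.5 FPKM, and its model overlaps another. The receptor gene PSY1R had 0.234 against 0.233 FPKM. Of the lower members, PSK2, PSK3 and BAK1 were thus within counting error.

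Known regulators of seed size had a median of -0.10 (interval -0.19 to 0.02, percentile 1.67), with 13 of 20 members lower. This value was unstable: it was -0.03 with no minimum FPKM, -0.06 with a minimum of 5 and -0.18 without the 50 most abundant genes. CYP78A9, a cytochrome P450 gene that promotes fruit and seed growth, was the only member past 2-fold, with 0.896 FPKM in GmPSKγ1 and 3.91 FPKM in the control. DWF4, of brassinosteroid synthesis, had 7.61 against 11.3 FPKM, IKU1 had 4.51 against 6.07 FPKM and ARF2 had 50.8 against 58.0 FPKM.

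Clock genes that peak in the morning were lower in GmPSKγ1 in 5 of 5 cases, with a median of -0.41 at percentile 0.26 (-0.66 with a pseudocount of 0.1). LHY had 3.39 against 5.89 FPKM and CCA1 had 3.01 against 4.89 FPKM. Evening clock genes had a median of 0.10 (percentile 68.6), with PRR5 at 5.24 against 3.18 FPKM, ELF4 at 5.72 against 3.90 FPKM (ratio interval 0.953 to 2.28) and TOC1 at 33.4 against 35.9 FPKM.

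**Figure D2:**
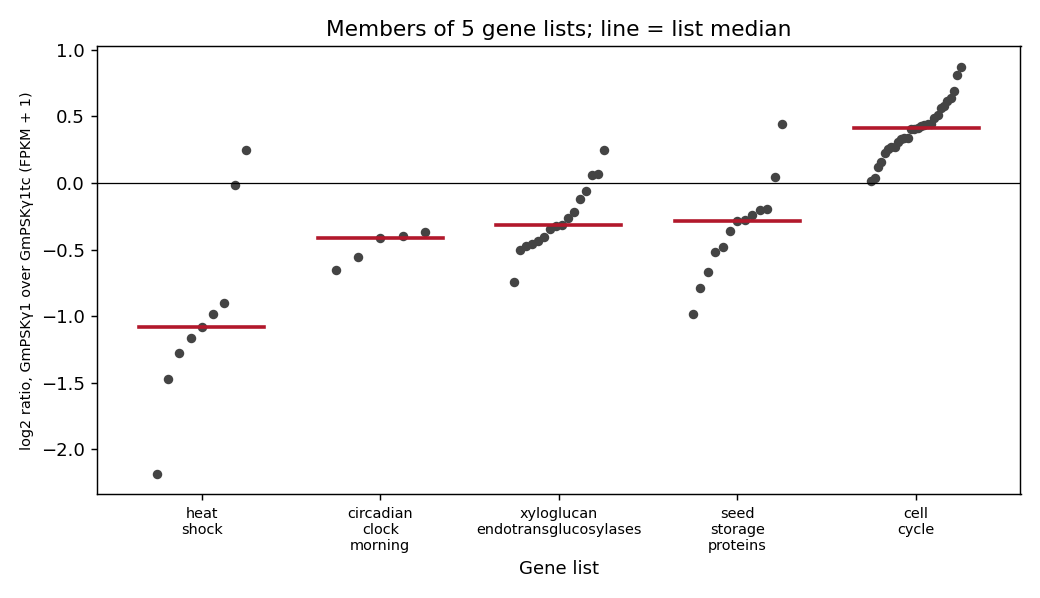
Log2 ratio of GmPSKγ1 over GmPSKγ1tc (y axis, FPKM + 1) of each measured member of 5 gene lists (x axis), with each point a gene and each red line the list median. The 28 cell cycle genes lie above 0 on the deposited scale (26 of 28 under 2 of the rescalings), the 5 morning clock genes lie below it, and 8 of 9 heat shock genes lie below it.

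Markers of seed compartments and of other tissues that the pools could hold were compared. None of these lists stood apart. Seed coat mucilage genes had a median of 0.05 (percentile 32.3), with MUM2 at 51.4 against 32.6 FPKM and MYB61 at 74.3 against 50.2 FPKM. Seed coat flavonoid genes had a median of 0.05 (percentile 30.4), with TT19 at 33.1 against 19.7 FPKM and LDOX at 29.9 against 18.7 FPKM, while the most abundant member TT10 had 597 against 682 FPKM. Endosperm markers had a median of -0.09 (percentile 6.25), with YUC10 at 15.4 against 25.1 FPKM, EPR1 at 3640 against 4261 FPKM and, the other way round, KRS at 42.4 against 32.8 FPKM. Embryo patterning genes had a median of -0.11 (percentile 4.33), with WOX9 at 19.6 against 14.1 FPKM and PDF1 at 542 against 607 FPKM. Markers of silique wall and leaf had a median of 0.00 (percentile 38.1), with the myrosinase gene TGG1 at 63.4 against 76.5 FPKM, TGG2 at 1.55 against 0.841 FPKM and CORI3 at 3.16 against 5.20 FPKM. Photosynthesis genes were higher in GmPSKγ1 for 23 of 26 members, with a median of 0.21 (interval 0.13 to 0.28), or 20 of 26 after rescaling without the 50 most abundant genes. At percentile 89.4 this list lay within the range of equally abundant genes, but it was at 99.7 among unmatched random lists. The 51 measured genes with photosystem in their annotated product, screened after the fact, lay above their matched range (median 0.27, percentile 99.99). PSAF had 729 against 507 FPKM and LHCB1.3 had 5065 against 4697 FPKM.

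Auxin, abscisic acid, jasmonate and salicylate lists did not stand apart. Auxin response genes had a median of 0.13 (percentile 76.6), with GH3.3 at 10.4 against 6.51 FPKM and IAA29 at 1.05 against 1.78 FPKM (ratio interval 0.328 to 1.03). Abscisic acid genes had a median of -0.09 (percentile 6.17), with CYP707A1 at 12.8 against 16.8 FPKM and HAI1 at 212 against 193 FPKM. Jasmonate response genes had a median of 0.16 (percentile 85.1), with THI2.1 at 1.84 against 0.683 FPKM. Of the salicylate list only ICS1 was measured, at 1.18 against 1.17 FPKM (log2 ratio 0.01, percentile 48.6). Commonly used reference genes had a median of 0.10 (percentile 63.1), with 11 of 13 higher, or 7 of 13 after rescaling without the 50 most abundant genes. EF1A had 648 against 518 FPKM.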

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

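With 1 library per genotype, no setting adds replicate error, and no paired analysis was possible because each group has a single library. Leaving out overlapping models, rescaling to the mean of the deposited sums, the suberin list and matching random lists on gene length were chosen after seeing the data. The numbers of genes past the threshold depended on how low values were treated. Against 73 higher and 146 lower genes, a pseudocount of 0.1 gave 179 and 231, a pseudocount of 5 gave 14 and 54, and a minimum mean FPKM of 5 gave 30 and 85. A 1.5-fold threshold gave 557 and 478, so the larger group changed from lower to higher genes, and a 4-fold threshold gave 11 and 29. Rescaling to a sum of 1000000 per library gave 113 higher genes. It multiplies the values by 1.45 in both libraries, and so weakens the pseudocount and the minimum; rescaling both to the mean of their deposited sums gave 75 and 145. Leaving out overlapping models gave 46 higher genes. The other 10 counts stayed within 1.5 times. No gene list outside the range of random lists changed the sign of its median under any alternative. The cell cycle median was 0.31 with a pseudocount of 5. The morning clock median was -0.66 and -0.30 with pseudocounts of 0.1 and 5. Some medians moved by over 1.5 times but stayed within their intervals. With a pseudocount of 5 the xyloglucan endotransglucosylase median was -0.15 (from -0.32) and that of seed size regulators -0.07 (from -0.10). The latter was -0.03 with no minimum, -0.06 with a minimum of 5 and -0.18 without the 50 most abundant genes. The phytosulfokine list was at -0.09 (from -0.15) with no minimum or as a mean, and the wound and touch list at -0.20 (from -0.12) without the 50 most abundant genes. The wound and touch list was no longer outside the random lists once these were also matched on length (percentile 2.86). With unmatched random lists, the late embryogenesis abundant (97.7) and photosynthesis (99.7) lists stood apart as well. Of lists within the random range, the median changed sign under rescaling by the median ratio or without the 50 most abundant genes for mucilage, salicylate, and silique wall and leaf lists, and under the latter alone for maturation regulators and flavonoids. It also changed sign for jasmonate genes with a minimum of 5, embryo patterning genes as a mean, and silique wall and leaf markers under both of these. Among the named genes that overlap no other model, 598 alternative log2 ratios stayed within counting error and 92 did not, none with a change of sign past 2-fold. The 3 rescalings moved the median of all genes by at most 0.07 (-0.07, without the 50 most abundant genes). Depth limits genes at a few reads: 3 reads correspond to 0.183 and 0.196 FPKM in a transcript of 1 kilobase.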

Other observations

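The tests of gene length and of the suberin list were set before their values were seen, and every other test in this part was chosen after the result had been seen. Gene families were screened after the fact by 34 keywords in the annotated products, 33 of them with a measured gene, and by 228 products with at least 8 measured genes each. Of the 33 keyword families, 15 had medians outside the central 95% of matched random lists, 6 above and 9 below. Of the 228 products, 42 did so, 19 above and 23 below, where chance would give 11.4 if genes were independent. Genes for ribosomal proteins were higher in GmPSKγ1 for 293 of 313 measured members, with a median log2 ratio of 0.35 (95% interval 0.33 to 0.37 over members), or for 272 of 313 after rescaling without the 50 most abundant genes. Photosystem genes were higher for 45 of 51 (median 0.27), proteasome genes for 38 of 42 (0.17) and thaumatin genes for 9 of 10 (0.39). In the other direction, laccase genes, whose products oxidise phenolic compounds, were lower for 7 of 7, with a median of -0.87 (interval -1.97 to -0.19). Arabinogalactan protein genes were lower for 27 of 40 (median -0.22), hydroxyproline-rich protein genes for 48 of 71 (-0.12), cellulose synthase genes for 12 of 15 (-0.16) and WRKY genes for 18 of 26 (-0.13). None of the families named here changed the sign of its median under the 3 rescalings. The histone (93.6) and defensin (89.4) families were inside the range once random lists were also matched on length. The kinesin (99.8), tubulin (97.65) and DNA replication and polymerase (99.6) families, inside the range before, were then above it.

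The genes lowest in GmPSKγ1 included esterase and membrane protein genes, which raised the hypothesis that suberin genes differ as a group. Suberin is the lipid polyester that seals the seed coat late in development. A list of 16 suberin genes was fixed after the lowest genes had been seen and before the values of its own members were looked at. Its 11 measured members had a median log2 ratio of -0.61 (interval -1.58 to -0.12), below all 10000 matched random lists. Of these, 10 of 11 were lower, 2 of them at least 2-fold, and the models of 3 members overlap another. GPAT5, the acyltransferase gene of suberin synthesis, had 0.127 FPKM in GmPSKγ1 and 2.95 FPKM in the control. The former is near the depth limit, where 3 reads correspond to 0.183 FPKM in a transcript of 1 kilobase. The transporter gene ABCG6 had 0.462 against 3.38 FPKM, CYP86B1 had 17.7 against 30.1 FPKM and ABCG20 had 58.6 against 86.3 FPKM. MYB107, a regulator of these genes, had 45.7 against 49.7 FPKM. This is consistent with a lower level of suberin transcripts in the GmPSKγ1 pool, and replication would be needed to assign it to the genotype.

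Of 61 measured models that share coordinates with another, such as GBF6 and bZIP2, 15 (24.6%, exact 95% interval 14.5% to 37.3%) were past 2-fold, against 1.22% of models that overlap another at other coordinates (interval 0.861% to 1.68%) and 1.13% of models that overlap none (interval 0.970% to 1.32%). Without the loci of the highest and lowest genes, which prompted this comparison, it was 6 of 48 (12.5%, interval 4.73% to 25.2%). Models at the same locus are not independent, so the intervals for shared coordinates are too narrow. By locus, 12 of 37 measured shared loci held a model past 2-fold. Counting error is argued against, since each of 100 Poisson draws gave 0 models with shared coordinates past 2-fold and the data gave 15. A different division of reads between the models is a candidate explanation: of 12 shared loci with a model past 2-fold, 8 were within 2-fold once both models were summed. The GBF6 locus was 1 of 4 that were not, at 143 against 0.763 FPKM summed, so a missed estimate in the control or a true difference both stay open there.

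The listed heat shock genes were lower in GmPSKγ1. Library scaling is argued against by its small size: the 3 rescalings moved the median of all genes by at most 0.07 (-0.07). They could therefore not bring the list near 0. The highest median of the 9 measured members under them was -1.10 (-0.98 with the minimum FPKM applied again). Warmth or handling of the control pool at harvest may account for the lower heat shock genes as well as the genotype. The wound and touch list had a median of -0.12, but its interval (-0.39 to 0.05) reaches the median of all genes. With 1 pool per genotype, handling and genotype cannot be told apart. Division of reads with unlisted paralogs stays open. The FPKM summed over the 84 measured genes with heat shock in their product had a log2 ratio of -0.35, between the bounds set for either outcome. That sum leaves out genes annotated as HSP20-like chaperones, so it misses small heat shock protein genes and cannot decide the question. Summed over the 21 measured HSP20-like genes, FPKM was 397 in GmPSKγ1 and 555 in the control (log2 ratio -0.49). The lower morning clock genes leave a different harvest hour open too, untested.

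Cell cycle genes were higher and storage protein genes lower in GmPSKγ1. The share of the library taken by the 50 most abundant genes is argued against as the whole cause of the former by its size. Rescaling without them took 0.08 off the cell cycle median and left 0.33 (interval 0.23 to 0.41). A gene length bias is argued against by a percentile of 100 among random lists matched on expression and length. An earlier developmental stage of the GmPSKγ1 pool might give both, and the lower suberin genes go with it, but late embryogenesis abundant genes had a median of 0.23 with an interval (-0.21 to 0.64) that spans the median of all genes, 0.05. Stage and genotype cannot be told apart here, because each genotype is 1 pool.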
